A study of Mus musculus with 16 samples.

How the data were processed

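Poly(A) RNA libraries were made for 16 samples of mouse jejunal organoids with a directional second-strand module, from 250 ng of total RNA, per the labels' protocols. Per the submitters' processing notes, bcl2fastq 1.8.4 and STAR 2.4.0f1 were used and the genome build was GRCm38. The counting tool, the annotation and the strand setting are not given in the sources used here. Genes that overlap on opposite strands are therefore uncertain. The authors deposited 1 table per day, each with whole-number read counts per gene for 8 libraries, a normalized value per library, and their own statistics. Per the file headers, these are a log2 fold change, an average log2 CPM, and p-values from DESeq and edgeR. The deposited normalized values are a score per gene that equals the count times nearly 1 factor per library, within 0.59% at day 2 and 0.54% at day 4 for the larger values. The deposited log2 fold change is 4OHT over DMSO: it lay within 0.006 (day 2) and 0.024 (day 4) of the log2 ratio of the normalized group means, for genes above a log2 CPM of 3.

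The deposited tables list 20790 genes at day 2 and 20658 at day 4, each with at least 10 reads summed over its 8 libraries. In the day 4 table, 661 cells held a comma as the decimal mark, which was read as a point, and 14 gene symbols had been rewritten as dates and were replaced through their gene ID. Of the gene IDs, 20670 and 20542 were found in GENCODE M21, whose GRCm38 coordinates are given here, 1-based. The authors' statistics are printed only as counts of calls, and all other values were computed from the deposited counts.

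Libraries were grouped by the labels' treatment and time point, with replicate numbers from the titles. Counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): TMM scaling, filterByExpr, robust quasi-likelihood fits, and Benjamini-Hochberg adjusted p below 0.05. Each treatment comparison used the 8 libraries of its day, each time comparison the 8 libraries of its treatment, and the interaction all 16 libraries. Standard errors are the log2 fold change divided by the square root of the F statistic. Library totals of 63.8 M to 93.3 M counts set the counting precision. Reads carry no molecular identifiers, so counting error alone understates the error. In each of the 24 pairs of libraries within a group, counts differed by more than counting noise, so none is a copy of another.

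The designs, 30 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Hnf4a and Wnt3 were always named. For each treatment comparison up to 10 of the largest rises and of the largest falls were named among genes with an adjusted p below 0.05, a mean log2 CPM of at least 3, no predicted gene name and no overlap between the groups. The 5 largest in each direction were named for the interaction, where overlap was allowed, and for each time comparison. From each list, the 2 members with the smallest p and the 2 with the highest mean log2 CPM could be named. Lists were tested with camera at an inter-gene correlation of 0.01 and with an estimated correlation. The fry test was also planned and run on each list. Its adjusted p is given for the treatment comparisons and the interaction where its call differed from that of camera at 0.01. The lists hold markers of Paneth (with and without defensins), stem, goblet, enteroendocrine, tuft, stromal and immune or endothelial cells, and genes of the pathways named in the results. Adjusted p-values of lists are over the lists of a comparison.

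Whether replicate numbers pair the libraries was checked from the deviations from group means of genes above a mean log2 CPM of 3. At day 4 the correlations of same-numbered DMSO and 4OHT libraries were 0.64 to 0.81, and all 8 libraries correlated best with their own number, so the numbers pair these libraries. The pairing comes from the data, since the labels name no shared batch. At day 2 the correlations were -0.11 to 0.49, and between days 0.07 to 0.19 in DMSO and -0.23 to 0.39 in 4OHT. Pairing by number was thus not detected there, which does not exclude it.

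The alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors in edgeR, no filter on low counts, a filter of at least 1 CPM in 4 libraries, a replicate block, an adjusted p below 0.01, a fold change of at least 1.5, every library thinned to the smallest total, a fit over all 16 libraries, and each library left out in turn. A block per replicate number and day for the interaction, and gene list tests with the block, were added after seeing the data. The tests were checked on simulated counts with 200 changed genes drawn from the real means, library sizes and dispersions. For the day 2 comparison, run on 15741 genes, edgeR recovered 42.0% of genes changed 1.25-fold, 72.0% at 1.5-fold, 84.0% at 2-fold and 98.0% at 4-fold, with 4 false calls among 152. For day 4, run on 15888 genes, it recovered 30.0%, 62.0%, 78.0% and 98.0%, with 6 false calls among 139. For the interaction, run on 16418 genes, it recovered 22.4%, 46.9%, 63.8% and 94.0%, with 1 false call among 112. For the time comparisons, 13 of 158 calls were false in DMSO, run on 15917 genes, and 14 of 154 in 4OHT, run on 15803 genes. Where same-numbered replicates were simulated to deviate together, 2 of 104 calls were false without the block and 15 of 145 (10.3%) with it. The shared deviation was drawn separately for each gene on top of the real day 4 dispersions. It was not matched to the real pairs. In that simulation the fit without the block recovered 0%, 42.9%, 66.0% and 100% of genes changed 1.25-, 1.5-, 2- and 4-fold, and the fit with the block 28.0%, 67.3%, 70.0% and 100%. In this simulation of the day 4 comparison, the larger blocked count thus held more true and more false calls. The recovery and the false shares need not be those of the real day 4 fits, and the blocked interaction was not simulated. DESeq2 had 15.6% to 19.6% false calls in these simulations.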

Results

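RNA was sequenced from epithelial organoids grown from mouse jejunum. The organoids carried CreERT2, a tamoxifen-activated recombinase under the Villin promoter, and loxP-flanked (floxed) alleles of Hnf4a, which encodes a nuclear receptor of the intestinal epithelium. Organoids received 0.5 µM 4-hydroxytamoxifen (4OHT), which activates the recombinase, for 24 h before they were split. Control organoids received the solvent DMSO. The labels give 4 groups of 4 libraries: DMSO and 4OHT at day 2 and at day 4. The labels' protocol names a harvest at day 4 after the last passage and gives no separate description of day 2. The days are therefore used here as the labels name them. Library totals ranged from 63.8 M to 93.3 M counts. The 10 most abundant genes took 5.04% to 6.11% of the counts of a library. Nothing in the labels says that replicates came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical. In the principal components of all 16 libraries, the first axis (67.3% of the variance) separated the days. On this axis, the 4OHT libraries of each day lay on the day 2 side of the DMSO libraries of that day. The second axis (16.8%) separated the treatments within each day. Positions on it at day 2 were 0.1 to 8.2 in 4OHT and -19.3 to -15.3 in DMSO. At day 4 they were 9.1 to 26.4 in 4OHT and -9.8 to -1.5 in DMSO. The library of 4OHT day 4 replicate 4 stood apart from the rest of its group, at 26.4 on the second axis against 9.1 to 17.6.

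**Figure D1:**
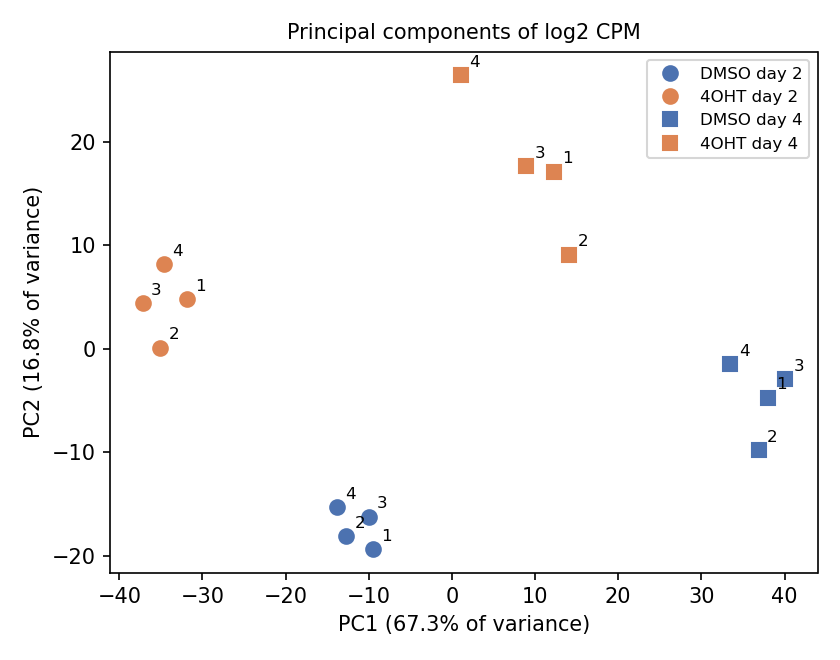
Principal components of log2 CPM of the 16 libraries, with the first axis (67.3% of the variance) across and the second (16.8%) upward. Each point is a library, colour gives the treatment, shape the day and the digit the replicate. 4OHT day 4 replicate 4 lies at 26.4 on the second axis.

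Hnf4a (ENSMUSG00000017950, GRCm38 chromosome 2, 163506808 to 163572910, plus strand), the gene targeted for deletion, was lower in every 4OHT library than in every DMSO library of the same day. It measured 1002 ± 31.6 CPM (TMM-scaled share of library counts; SD, n = 4) in DMSO and 504 ± 22.9 in 4OHT at day 2, and 982 ± 12.5 and 477 ± 15.5 at day 4. The log2 fold changes were -0.99 ± 0.05 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 8.25e-08) and -1.04 ± 0.05 (edgeR adjusted p = 1.14e-06), which left 50.3% and 48.6% of the control level. These counts are per gene and include any exons outside the floxed part. Wnt3 (ENSMUSG00000000125, GRCm38 chromosome 11, 103774150 to 103817957, plus strand), which encodes a secreted Wnt ligand made by Paneth cells and is named in the series title, fell from 9.11 ± 1.245 to 4.58 ± 0.371 CPM at day 2 and from 16.9 ± 0.622 to 8.63 ± 0.252 CPM at day 4. Its log2 fold changes were -0.99 ± 0.10 (edgeR adjusted p = 1.96e-05) and -0.97 ± 0.06 (edgeR adjusted p = 6.40e-06).

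**Figure D2:**
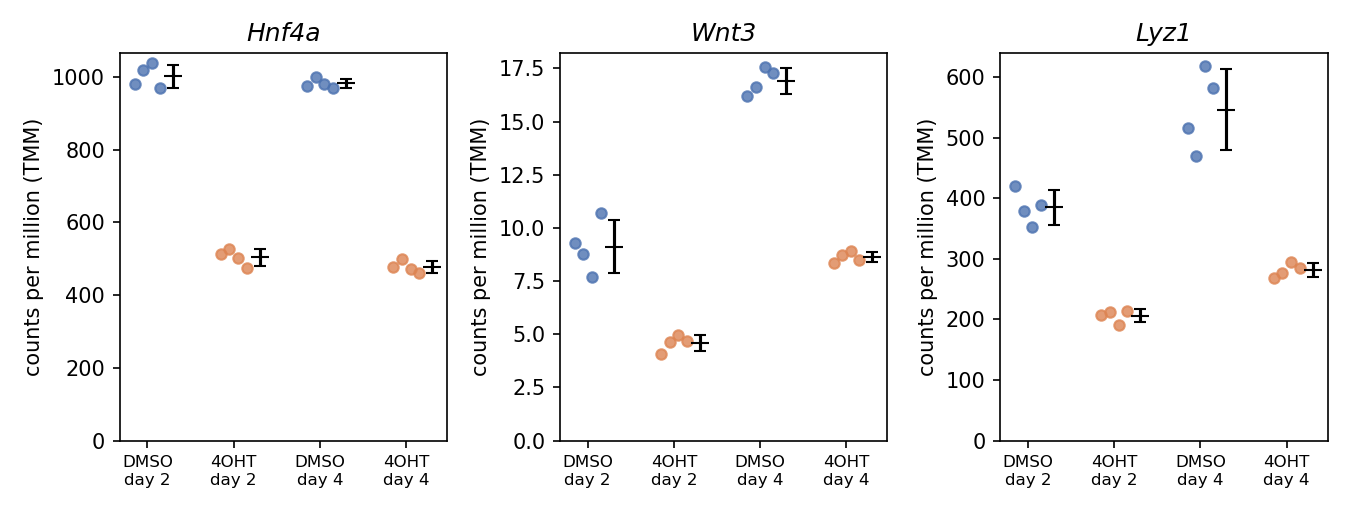
CPM (TMM-scaled within each day) of Hnf4a, Wnt3 and the Paneth cell lysozyme Lyz1 in each library. Points are the 4 libraries of a group, and the bar beside them is the mean with the SD; Hnf4a fell from a mean of 1002 to 504 CPM at day 2 and from 982 to 477 at day 4.

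At day 2, the comparison of 4OHT with DMSO asked how organoids treated to delete Hnf4a differed early from control organoids. Among genes above a mean log2 CPM of 3 whose groups did not overlap, the largest rises included Tff1 and Mal. Tff1, a mucosal trefoil peptide of the stomach, rose from 8.22 ± 0.83 to 118 ± 14.9 CPM (log2 3.84 ± 0.10). Mal, Anxa8, Krt4, Cav2, Ly6d, Sprr1a, Fut2, Aqp3 and Mtcl1 rose by log2 3.45 to 1.75. The largest falls included Cps1, a mitochondrial enzyme of the urea cycle (994 ± 58.7 to 310 ± 27.7 CPM, log2 -1.68 ± 0.07), Acta1, Fbp1, an enzyme of gluconeogenesis, Msi1, Slc1a1, Lct, the brush border lactase, Mt2, Enpp7 and Dnase1 (log2 -1.65 to -1.23). By edgeR, 2681 genes rose and 2269 fell of 15897 tested, 435 and 119 of them at least 2-fold. The authors' deposited table gives 2653 higher and 2361 lower at an edgeR adjusted p below 0.05, and 2211 and 1701 by DESeq.

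Genes of Paneth cells, the granule-bearing cells at the crypt base, were mostly lower at day 2. Of 24 measured members, 16 fell and 1 rose, and 19 and 1 adjusted over the list alone (median log2 -0.41). Lyz1 fell from 385 ± 28.4 to 206 ± 10.7 CPM (log2 -0.90 ± 0.06) and Defa24 from 504 ± 81.4 to 370 ± 19.0 CPM (log2 -0.45 ± 0.09), while Nupr1 rose (log2 1.15 ± 0.07). Itln1 fell by 0.23 on the log2 scale, and this call ended without 4OHT day 2 replicate 3 (edgeR adjusted p = 0.0583). Defensin genes are near-identical copies whose reads may be shared between them; of the 14 members that are not defensins, 7 fell and 1 rose (9 and 1 adjusted over the list alone). The camera test placed the list below other genes (adjusted p = 1.56e-05; without defensins 0.00337), and both calls were lost with an estimated correlation (adjusted p = 0.545 for each).

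Most stem cell genes fell as well, and more Wnt target genes fell than rose. Of 19 stem cell genes, 13 fell and 3 rose, the same numbers adjusted over the list alone (median log2 -0.49). For this list, the camera adjusted p was 5.46e-08, and adjusted p = 0.447 with an estimated correlation. Olfm4, a marker of crypt base cells, fell by 0.95 and Clca3b by 0.63 on the log2 scale. Of 19 Wnt target genes, 7 fell and 1 rose, also adjusted over the list alone (median log2 -0.17). By camera the adjusted p was 0.0282, and adjusted p = 0.667 with an estimated correlation. The Wnt target list did not pass fry (adjusted p = 0.151). Axin2, a feedback inhibitor of Wnt signalling, fell by 0.72 and Sox9 by 0.44 on the log2 scale, whereas Ccnd1, a cyclin, rose (log2 0.57 ± 0.08). The Wnt ligand and receptor list also holds genes that are neither, Egf, Tgfa, Dll1 and Dll4 among them. Of its 23 measured genes, 10 rose and 4 fell (11 and 6 adjusted over the list alone). The rises included Wnt4 (0.978 ± 0.0915 to 8.90 ± 1.37 CPM, log2 3.19 ± 0.13) and Wnt7b (log2 2.94 ± 0.22). The receptor gene Fzd5 measured log2 0.02 ± 0.06. The list passed camera (adjusted p = 0.0445) but not with an estimated correlation (adjusted p = 0.545).

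Genes of fetal intestine and regenerating epithelium rose together at day 2: 26 of 31 rose and 1 fell, also adjusted over the list alone (median log2 1.01). The camera adjusted p was 6.07e-36, and adjusted p = 0.156 with an estimated correlation. Msln rose from 276 ± 19.5 to 827 ± 51.9 CPM, Krt7 from 1259 ± 72.3 to 2581 ± 149 CPM and Krt19 from 4088 ± 311 to 5717 ± 196 CPM. Of 19 gastric, colonic and squamous genes, 10 rose and 5 fell, also adjusted over the list alone (median log2 0.83), and this call held with an estimated correlation (camera adjusted p = 9.84e-12, and adjusted p = 0.0387 with an estimated correlation). It did not hold with an estimated correlation in the fit with the replicate block (adjusted p = 0.237). Of 29 p53 targets, which respond to DNA damage, 22 rose and 1 fell, also adjusted over the list alone (median log2 0.25). For this list, the camera adjusted p was 2.48e-07, and adjusted p = 0.270 with an estimated correlation. Ccng1 rose by log2 0.57 ± 0.05, Tnfrsf10b by 0.52 ± 0.04 and Cdkn1a by 0.25 ± 0.05; the Cdkn1a call ended in a fit over all 16 libraries (edgeR adjusted p = 0.188). Goblet cell genes rose in 13 of 23 cases and fell in 2 (14 and 3 adjusted over the list alone; median log2 0.29, camera adjusted p = 3.13e-06, and adjusted p = 0.496 with an estimated correlation), with Clca1 at 471 ± 15.4 and 1012 ± 64.5 CPM, Bcas1 at log2 1.13 ± 0.05 and the mucus protein gene Fcgbp at log2 0.71 ± 0.10.

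In lists of absorptive enterocyte genes and their metabolism, more members fell than rose at day 2. Of 31 brush border and digestive enzyme genes, 13 fell and 3 rose, also adjusted over the list alone (median log2 -0.22); Ggt1 fell by 0.96, Sis, the sucrase-isomaltase gene, fell by 0.52, and Vil1 measured log2 -0.01 ± 0.06. The Sis call ended without DMSO day 2 replicate 1 (edgeR adjusted p = 0.0755). Of 26 nutrient transporter genes, 13 fell and 3 rose (15 and 3 adjusted over the list alone), of 29 lipid absorption genes 10 fell and 3 rose (15 and 3), of 34 fatty acid oxidation genes 13 fell and 2 rose (13 and 2) and of 46 xenobiotic and steroid metabolism genes 26 fell and 5 rose (32 and 5). Gstm1 fell by 0.43 on the log2 scale, while Akr1b8 (log2 0.84 ± 0.05) and Gsta4 (log2 0.72 ± 0.05) rose. Of 42 oxidative phosphorylation genes, 29 fell and 0 rose (38 and 0 adjusted over the list alone; median log2 -0.19), as did Uqcrq, a subunit of complex III, by 0.34. These 6 lists passed camera, with adjusted p of 0.00208, 0.000228, 0.00811, 0.00867, 0.000222 and 1.82e-06 in the order given. With an estimated correlation the adjusted p was 0.667 for each except the nutrient transporters, for which it was 0.545. By fry the brush border, lipid absorption, fatty acid oxidation and xenobiotic lists did not pass (adjusted p = 0.0963, 0.125, 0.112 and 0.1005).

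Of 31 glycolysis and hypoxia genes, 12 rose and 2 fell, also adjusted over the list alone (median log2 0.20). By camera the adjusted p was 0.0188, and adjusted p = 0.667 with an estimated correlation. Among them Hk1, a hexokinase, rose by log2 1.22 ± 0.06. Of 44 cell cycle genes, 12 fell and 1 rose, also adjusted over the list alone (median log2 -0.10, camera adjusted p = 0.00370, and adjusted p = 0.667 with an estimated correlation); Stmn1 fell by 0.64, and the proliferation gene Mki67 measured log2 0.08 ± 0.08. Of 30 cell junction genes 15 rose and 5 fell (16 and 5 adjusted over the list alone), of 19 BMP signalling genes 7 rose and 3 fell (8 and 4), of 27 immediate early and heat shock genes 8 rose and 3 fell (8 and 3) and of 24 antimicrobial and MHC class II genes 10 fell and 5 rose (11 and 5). Their camera adjusted p values were 0.0440, 0.0432, 0.0356 and 0.0440, and with an estimated correlation the adjusted p was 0.311, 0.311, 0.490 and 0.545. With the replicate block the cell junction list did not pass camera (adjusted p = 0.0674). Of 35 intestinal transcription factor genes, 7 rose and 6 fell (8 and 7 adjusted over the list alone), among them Foxa1 (log2 0.64 ± 0.07) and Sox4 (log2 -0.58 ± 0.06). The transcription factors did not pass camera. Nor did the lists of enteroendocrine (2 rose and 3 fell of 30), tuft (2 and 2 of 21), stromal (1 and 0 of 3) and immune and endothelial cells (1 and 2 of 9), interferon response (4 and 2 of 29), cholesterol synthesis (2 and 2 of 25), iron and haem (3 and 6 of 22) and mitochondrially encoded genes (0 and 0 of 15). With the replicate block iron and haem genes passed camera (adjusted p = 0.0419), but not with an estimated correlation (adjusted p = 0.524). Adjusted over the list alone, the latter 8 lists gave 2 and 2, 2 and 2, 1 and 1, 1 and 2, 4 and 2, 2 and 2, 3 and 6, and 0 and 0. By fry, iron and haem genes passed (adjusted p = 0.00507). Glycolysis and hypoxia and cell cycle genes did not pass fry (adjusted p = 0.0607 and 0.0653).

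**Figure D3:**
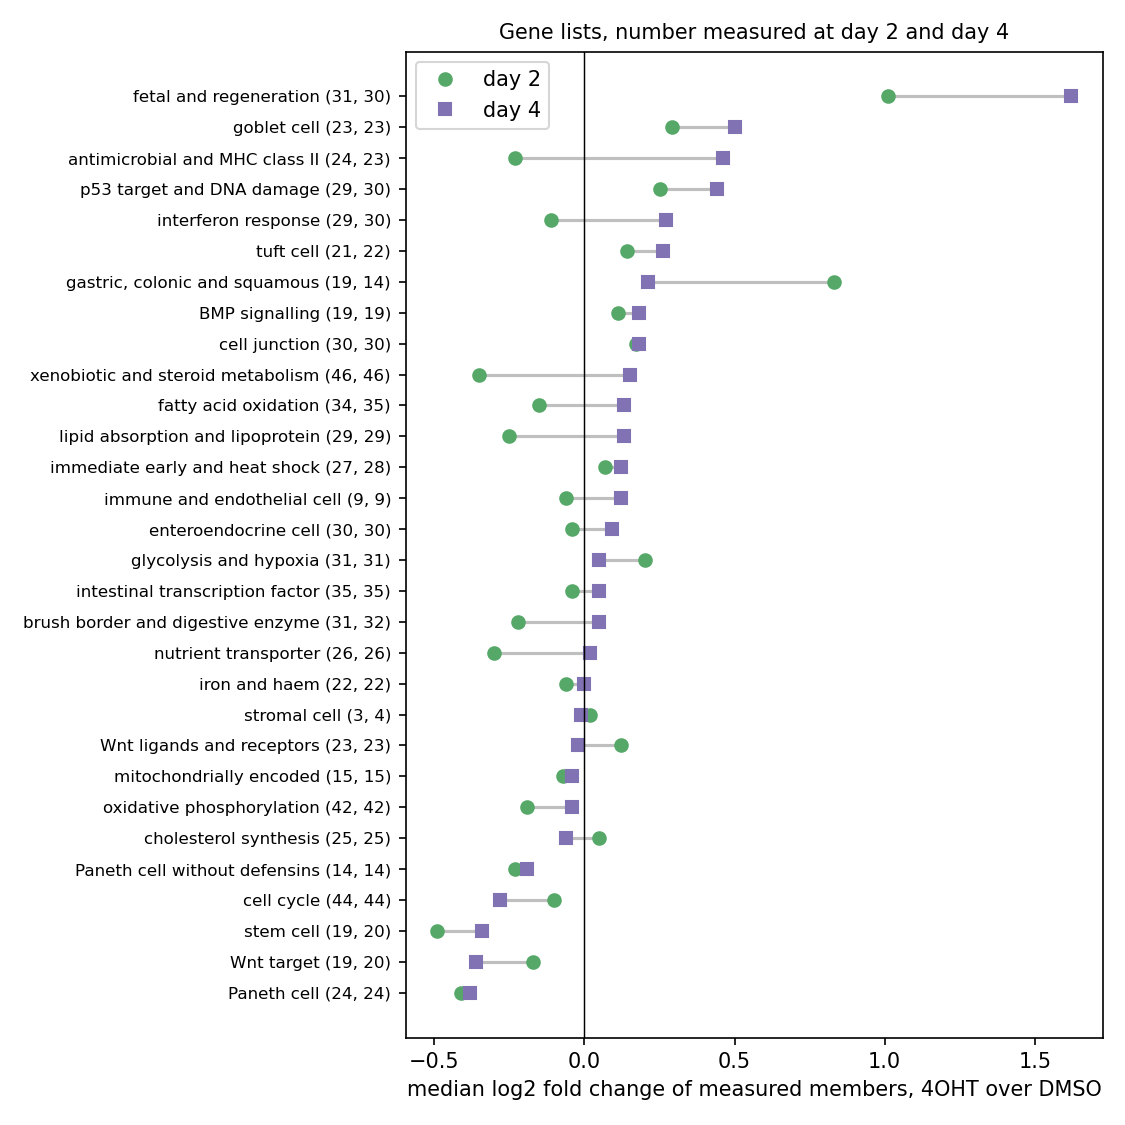
Median log2 fold change (4OHT over DMSO) of the measured members of each gene list at day 2 (circles) and day 4 (squares), with the numbers measured in parentheses. The fetal and regeneration list lies highest at both days, at 1.01 and 1.62, and the Paneth cell list lies at -0.41 and -0.38.

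At day 4, the same comparison asked what the change looked like later. Among genes above the same mean log2 CPM whose groups did not overlap, the largest rises were in Ly6d (3.10 ± 1.45 to 44.4 ± 30.6 CPM, log2 3.86 ± 0.52), Krt4 (log2 3.25 ± 0.38), Sptssb, Capg, Il1rn, Fut2, Lgals3, Ly6a, Msln and Syt8 (log2 2.94 to 2.48). The largest falls included Slc1a1, a glutamate transporter (51.4 ± 4.88 to 17.3 ± 2.27 CPM, log2 -1.57 ± 0.10), Cps1 (2225 ± 50 to 764 ± 116 CPM, log2 -1.54 ± 0.10), Vwa2 (log2 -1.30), Prss12, Mcoln2, Mt2, Bend7, Podxl (log2 -1.11) and Dnah8. By edgeR, 2191 genes rose and 1776 fell of 16040 tested, 486 and 129 of them at least 2-fold. Same-numbered libraries of this day deviated together, and with the replicate number as a block 3651 genes rose and 3565 fell. The day 4 values of single genes and lists are from the fit without the block, except where the block is named. The authors' deposited table gives 2106 higher and 1644 lower at an edgeR adjusted p below 0.05, and 1500 and 906 by DESeq.

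Most Paneth cell genes were also lower at day 4. Of 24 measured members, 14 fell and 2 rose (16 and 2 adjusted over the list alone; median log2 -0.38), with Lyz1 at 547 ± 66.1 and 281 ± 12.0 CPM (log2 -0.96 ± 0.08), Defa20 at log2 -0.59 ± 0.07, Defa24 at log2 -0.51 ± 0.07 and Clps at log2 -0.70 ± 0.09. Itln1 measured log2 -0.04 ± 0.07. Of the 14 members that are not defensins, 5 fell and 2 rose (6 and 2 adjusted over the list alone). The camera adjusted p was 4.81e-08 for the list and 0.0119 without defensins, and with an estimated correlation the adjusted p was 0.173 and 0.348. Of 20 Wnt target genes, 13 fell and 0 rose (14 and 0 adjusted over the list alone; median log2 -0.36), with Apcdd1 at log2 -1.16 ± 0.13 and Cdca7 at log2 -0.43 ± 0.05. Of 20 stem cell genes, 14 fell and 0 rose (14 and 2 adjusted over the list alone; median log2 -0.34), with Ascl2 at log2 -0.79 ± 0.09 and Olfm4 at log2 -0.58 ± 0.08. Both lists passed camera (adjusted p = 4.81e-08 and 1.12e-07) but not with an estimated correlation (adjusted p = 0.173 and 0.179). Of 23 genes of the Wnt ligand and receptor list, 6 rose and 6 fell (7 and 6 adjusted over the list alone), with Wnt4 at log2 3.27 ± 0.23. The list did not pass camera (adjusted p = 0.604), where the median and the test were negative (-0.02) and the mean positive (0.14).

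Cell cycle genes fell in 36 of 44 cases and rose in 0 at day 4 (36 and 1 adjusted over the list alone; median log2 -0.28, camera adjusted p = 3.08e-14, and adjusted p = 0.173 with an estimated correlation). Stmn1 fell by 0.53 and Tyms, which makes thymidylate, by 0.33; Top2a fell by 0.31, a call that ended without DMSO day 4 replicate 1 (edgeR adjusted p = 0.0673) or replicate 2 (edgeR adjusted p = 0.0581). Fetal and regeneration genes rose in 23 of 30 cases and fell in 1 (24 and 1 adjusted over the list alone; median log2 1.62, camera adjusted p = 1.80e-15, and adjusted p = 0.236 with an estimated correlation), with Anxa8 at 0.876 ± 0.572 and 15.2 ± 6.11 CPM. In 4OHT day 4 replicate 4, the library that stood apart, the mean of this list lay 0.53 above its group mean on the log2 scale. Of 30 p53 targets, 22 rose and 0 fell, also adjusted over the list alone (median log2 0.44). For this list, the camera adjusted p was 7.62e-13, and adjusted p = 0.173 with an estimated correlation. Among them Plk2 rose by log2 1.10 ± 0.09, Zmat3 by 0.98 ± 0.08 and Ccng1 by 0.92 ± 0.16. Of 14 gastric, colonic and squamous genes, 6 rose and 3 fell, also adjusted over the list alone (median log2 0.21, mean log2 1.24, camera adjusted p = 0.0215, and adjusted p = 0.173 with an estimated correlation), with Tff1 at log2 4.64 ± 0.41.

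Goblet cell genes rose further in number: 16 of 23 rose and 1 fell (16 and 2 adjusted over the list alone; median log2 0.50). Zg16 rose from 149 ± 11.9 to 624 ± 41.4 CPM and Clca1 from 126 ± 11.8 to 483 ± 18.7 CPM. This list passed camera with the preset correlation (adjusted p = 2.85e-19) and with an estimated correlation (adjusted p = 0.0186), but not with an estimated correlation in the fit with the replicate block (adjusted p = 0.0709). Antimicrobial and MHC class II genes rose in 11 of 23 cases and fell in 1 (12 and 1 adjusted over the list alone; median log2 0.46, camera adjusted p = 9.22e-08, and adjusted p = 0.105 with an estimated correlation), with the secreted lectins Reg3g (82.9 ± 9.55 to 397 ± 19.2 CPM) and Reg1 (45.5 ± 4.20 to 156 ± 10.7 CPM). Of 46 xenobiotic and steroid metabolism genes, 20 rose and 2 fell (22 and 2 adjusted over the list alone; camera adjusted p = 3.12e-05, and adjusted p = 0.259 with an estimated correlation), with Akr1b8 at log2 1.83 ± 0.17 and Ces2a at log2 0.64 ± 0.07. Of 35 fatty acid oxidation genes 11 rose and 2 fell (14 and 4 adjusted over the list alone), of 30 interferon response genes 8 rose and 1 fell (8 and 2), with Oas2 at log2 1.94 ± 0.27, and of 30 cell junction genes 14 rose and 2 fell (20 and 2). Their camera adjusted p was 0.0144, 0.00401 and 0.00950, and with an estimated correlation the adjusted p was 0.561, 0.475 and 0.561.

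Of 32 brush border and digestive enzyme genes, 9 rose and 3 fell at day 4 (12 and 3 adjusted over the list alone). They did not pass camera (adjusted p = 0.0892). Among them were Alpi, the intestinal alkaline phosphatase, at log2 0.94 ± 0.10, Dpp4 at log2 -0.38 ± 0.04 and Sis at log2 -0.01 ± 0.11. Of 29 lipid absorption genes, 8 rose and 1 fell, also adjusted over the list alone. By camera the adjusted p was 0.0513, and 0.0227 with the replicate block. With an estimated correlation the camera adjusted p was 0.520 without and 0.698 with the block. By fry the brush border and lipid absorption lists passed (adjusted p = 0.0288 for each). The nutrient transporters (4 rose and 2 fell of 26), enteroendocrine (5 and 1 of 30), tuft (3 and 0 of 22), stromal (1 and 0 of 4) and immune and endothelial cell lists (0 and 0 of 9) did not pass camera. Nor did BMP signalling (8 and 3 of 19), immediate early and heat shock (7 and 0 of 28), iron and haem (3 and 6 of 22), cholesterol synthesis (0 and 0 of 25), oxidative phosphorylation (0 and 1 of 42), glycolysis and hypoxia (1 and 0 of 31), mitochondrially encoded (1 and 0 of 15) or transcription factor genes (9 and 6 of 35). Adjusted over the list alone these 13 lists gave 4 and 2, 4 and 1, 0 and 0, 1 and 0, 0 and 0, 8 and 3, 7 and 0, 3 and 6, 0 and 0, 0 and 0, 0 and 0, 0 and 0, and 10 and 7. Of these lists, BMP signalling and iron and haem passed fry (adjusted p = 0.00525 and 0.0346). With the replicate block, glycolysis and hypoxia gave 5 and 6, oxidative phosphorylation 1 and 7 and cholesterol synthesis 0 and 4. Transcription factors gave 12 and 13 and nutrient transporters 10 and 2 with it, and immune and endothelial genes again 0 and 0. None of the 13 passed camera with the block. Median, mean and test differed in sign for nutrient transporters (0.02, -0.01, lower), glycolysis and hypoxia (0.05, 0.06, lower), stromal (-0.01, 0.23, higher) and mitochondrially encoded genes (-0.04, -0.03, higher). Among these were Sst (log2 1.23 ± 0.22) and Ghrl (log2 0.71 ± 0.08), hormones of enteroendocrine cells, Id4 (log2 1.56 ± 0.13) of the BMP list, and Hnf4g, the paralog of Hnf4a (190 ± 14.3 to 272 ± 8.87 CPM, log2 0.51 ± 0.06). Among 15498 genes tested at both days, which share no libraries, 1445 rose at both and 925 fell at both. Independent lists of these sizes would share 362 and 254, and 33 changed in opposite directions.

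Whether the 4OHT effect differed between the days was tested as an interaction over all 16 libraries. Reg3g (log2 1.82 ± 0.21), Pear1 (1.62 ± 0.18) and Mptx1 (1.48 ± 0.26) had the more positive effect at day 4, and Fgfr4, a growth factor receptor (-1.04 ± 0.13), Timp2 (-0.95 ± 0.15) and Rgs12 (-0.92 ± 0.12) the more negative one. Capg, Sptssb, Ptpn14 and Phldb2 also passed (log2 1.67, 1.49, -0.86 and -0.86), but their calls ended in 10, 10, 11 and 9 of the 16 fits that left out a library. Of xenobiotic and steroid metabolism genes, 19 of 46 had a more positive effect at day 4 and 0 a more negative one (38 and 0 adjusted over the list alone; median log2 0.51, camera adjusted p = 9.57e-35, and adjusted p = 0.0755 with an estimated correlation). Of antimicrobial and MHC class II genes, 8 of 24 did (14 adjusted over the list alone; median log2 0.59), and this list passed with the preset and with an estimated correlation (adjusted p = 3.12e-19 and 0.00580). By edgeR, 199 genes had a more positive and 79 a more negative effect at day 4, of 16597 tested. That total of 278 was 94 without 4OHT day 2 replicate 3 and 727 without DMSO day 2 replicate 4. It was 1850 with a replicate block within each day and 836 by DESeq2.

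The change from day 2 to day 4 in DMSO organoids shows how control organoids changed over the same interval. Genes induced by low oxygen and glycolysis rose, led by Bnip3 (log2 3.23 ± 0.32), Ak4 (3.15 ± 0.38), Slc16a3, a lactate transporter (2.56 ± 0.34), and Ankrd37 (2.51 ± 0.17), along with Lct (2.63 ± 0.13). Of 31 glycolysis and hypoxia genes 26 rose and 0 fell, of 24 Paneth cell genes 19 rose and 0 fell, of 20 Wnt target genes 18 rose and 1 fell, and of 20 stem cell genes 19 rose and 0 fell (median log2 0.99, 0.70, 1.11 and 1.08; adjusted over the list alone 26 and 0, 19 and 1, 18 and 1, and 19 and 0). Lgals3 (log2 -3.57 ± 0.19), Anxa10 (-3.51 ± 0.26), Cyp2c29 (-3.34 ± 0.12), Msln (-3.28 ± 0.30) and Krt4 (-3.19 ± 0.28) were among the largest falls. Fetal and regeneration genes fell in 25 of 30 cases and rose in 1 (median log2 -1.98), and xenobiotic and steroid metabolism genes fell in 35 of 46 and rose in 6 (median log2 -0.57). Adjusted over the list alone these were 25 and 1, and 36 and 6. These 6 lists passed camera (adjusted p = 2.60e-13, 2.29e-08, 1.41e-14, 2.37e-25, 2.94e-26 and 1.68e-24 in the order given). None passed with an estimated correlation (adjusted p = 0.355, 0.330, 0.175, 0.0659, 0.0923 and 0.0659). Enteroendocrine genes rose in 18 of 30 cases and tuft cell genes in 13 of 21, and 0 fell in either list. Adjusted over the list alone 20 and 14 rose. Both lists passed camera (adjusted p = 0.00254 and 0.000829) but not with an estimated correlation (adjusted p = 0.607 and 0.499). Of 29 p53 targets, 22 fell with time and 0 rose (24 and 0 adjusted over the list alone; median log2 -0.41, camera adjusted p = 1.58e-09, and adjusted p = 0.0659 with an estimated correlation). By edgeR, 4616 genes rose and 3989 fell of 16088 tested. The tables list only genes with at least 10 reads over the 8 libraries of a day, and the comparison between days used the 19964 genes listed at both.

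In 4OHT organoids, the largest rises from day 2 to day 4 among genes above a mean log2 CPM of 3 were in Lct (log2 3.38 ± 0.33), Fbp1 (3.10 ± 0.16), Bst1 (2.71 ± 0.10) and the apolipoprotein genes Apoc3 (2.68 ± 0.11) and Apoa4 (2.64 ± 0.18). The largest falls were in Cyp2c29 (-3.27 ± 0.18), Psca (-3.02 ± 0.27), Mal (-2.75 ± 0.23), Sprr1a (-2.59 ± 0.35) and Krt4 (-2.38 ± 0.28). Of 24 Paneth cell genes 21 rose and 0 fell, and of 31 fetal and regeneration genes 23 fell and 1 rose (median log2 0.73 and -1.34; 21 and 0, and 25 and 1, adjusted over the list alone). Both passed camera (adjusted p = 9.36e-14 for each) but not with an estimated correlation (adjusted p = 0.0675 and 0.506). The rise was not particular to Paneth cell genes. Of 20 stem cell genes 17 rose and 1 fell, of 30 enteroendocrine genes 24 and 0, and of 22 tuft cell genes 14 and 0. Adjusted over the list alone these were 18 and 1, 24 and 0, and 15 and 0. These lists passed camera (adjusted p = 9.30e-29, 6.69e-07 and 0.000475) but not with an estimated correlation (adjusted p = 0.0576, 0.506 and 0.506). Xenobiotic and steroid metabolism genes rose in 8 of 46 cases and fell in 14, also adjusted over the list alone (median log2 0.00, camera adjusted p = 0.122). By edgeR, 4127 genes rose and 3753 fell of 15962 tested. Among 15685 genes tested in both treatments, 3213 rose with time in both and 2753 fell in both, where independent lists would share 1171 and 932.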

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

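The test without glycolysis and hypoxia genes and the thinning test were set before their results were seen; the pairing itself was seen first. Each group of 4 libraries was searched, for each gene named in the text and for the library total, for a library far from the other 3. Of 420 such tests, 11 (2.6%) met the limit, where chance gives about 1 in 20.

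In DMSO day 4 replicate 4, 5 genes lay above the other 3 libraries: Anxa8 at 1.73 CPM (others 0.530 to 0.692), Ly6d at 5.26 CPM (others 2.22 to 2.56), Msln at 49.7 CPM (others 20.9 to 24.3), Anxa10 at 19.4 CPM (others 8.53 to 9.69) and Ptpn14 at 12.7 CPM (others 9.87 to 9.97). In 4OHT day 4 replicate 4, Aqp3 was higher at 19.5 CPM (others 15.1 to 15.8) and Olfm4 lower at 1331 CPM (others 1578 to 1593). At day 2, Sox9 was lower at 63.0 CPM in DMSO replicate 3 (others 73.4 to 74.7). Cdkn1a was lower at 202 CPM in DMSO day 2 replicate 4 (others 228 to 233) and higher at 280 CPM in 4OHT day 2 replicate 2 (others 261 for each). Itln1 was lower at 571 CPM in 4OHT day 2 replicate 3 (others 637 to 646).

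Same-numbered DMSO and 4OHT libraries of day 4 deviated together from their group means, with correlations across genes of 0.64 to 0.81, and in both libraries of replicate 4 the fetal and regeneration list lay above its group mean, by 0.29 and 0.53 on the log2 scale. A shared sequencing depth is argued against, since the lowest of the 4 correlations was 0.63 after every library was thinned to the smallest total. Genes of glycolysis and hypoxia as the only carriers are argued against as well, since the lowest correlation was 0.61 without that list and the genes most correlated with it. A shared handling batch or a shared source culture stays open and was not tested, since the labels name neither, and no biological explanation was tested.

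The 4OHT effect differed between the days by the interaction test for 23 genes named in the text. The effect was more positive at day 4 for Reg3g (log2 1.82), Capg (1.67), Pear1 (1.62), Sptssb (1.49), Mptx1 (1.48), Syt8 (1.28), Akr1b8 (0.99), Ces2a (0.88), Reg1 (0.86), Clca1 (0.84), Fut2 (0.80), Zg16 (0.80), Alpi (0.72), Gsta4 (0.67), Gstm1 (0.64) and Zmat3 (0.41). It was more negative for Apcdd1 (-1.48), Fgfr4 (-1.04), Timp2 (-0.95), Rgs12 (-0.92), Ptpn14 (-0.86), Phldb2 (-0.86) and Ccnd1 (-0.56).

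By camera with the preset correlation, 18 lists differed in their 4OHT effect between the days. The median difference was 0.68 for fetal and regeneration, 0.59 for antimicrobial and MHC class II, 0.53 for gastric, colonic and squamous, 0.51 for xenobiotic and steroid metabolism, 0.43 for lipid absorption, 0.41 for nutrient transporters, 0.37 for brush border and for interferon response, 0.29 for immune and endothelial, 0.26 for fatty acid oxidation, 0.23 for goblet, 0.16 for enteroendocrine, 0.15 for oxidative phosphorylation and 0.14 for p53 target genes. It was -0.17 for cell cycle, -0.14 for Wnt ligands and receptors, -0.09 for Wnt targets and -0.09 for cholesterol synthesis. No single member passed over all genes in the fetal, gastric, lipid absorption, nutrient transporter, immune and endothelial, enteroendocrine, oxidative phosphorylation, cell cycle and cholesterol synthesis lists. Adjusted over the list alone, 9 fetal, 16 lipid absorption, 9 nutrient transporter, 3 immune and endothelial, 1 gastric and 1 cell cycle genes did. Of these 18, the antimicrobial and MHC class II list alone passed with an estimated correlation (adjusted p = 0.00580, and 0.00634 with a replicate block within each day). With that block and the preset correlation, immune and endothelial genes no longer passed (camera adjusted p = 0.0278 without and 0.0763 with the block). Glycolysis and hypoxia genes then passed (0.139 without and 0.00729 with it), but not with an estimated correlation (adjusted p = 0.631). By fry without the block, the fetal and regeneration, p53 target and Wnt target lists did not pass (adjusted p = 0.216, 0.122 and 0.217). Nor did the enteroendocrine, oxidative phosphorylation and cholesterol synthesis lists (fry adjusted p = 0.224, 0.216 and 0.496).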

How the results depend on the processing

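The replicate block within each day and the list tests with the block were chosen after seeing the data. No single gene or list changed direction under the alternatives run where the main fit or the alternative called it. The balance of genes turned for time in DMSO. There 4616 genes rose and 3989 fell in the main fit, and 4122 rose and 4190 fell with every library thinned. Hnf4a ranged from -1.02 to -0.97 at day 2 and from -1.06 to -1.02 at day 4, and Wnt3 from -1.08 to -0.92 and from -1 to -0.95, past the threshold in every alternative. At an adjusted p below 0.01 the counts were 2976 at day 2, 2188 at day 4 and 28 for the interaction. With a fold change of at least 1.5 they were 1391 at day 2, 1266 at day 4, 133 for the interaction, 3148 for time in DMSO and 2857 for time in 4OHT, and 5 and 8 Paneth cell members at day 2 and day 4; a stricter threshold keeps fewer genes by construction. DESeq2 gave 836 genes for the interaction. With the replicate block the counts were 4916 at day 2, 7216 at day 4 (3961 of the 3967 without it), 889 for the interaction (1850 with a block per day), 8665 for time in DMSO and 7967 for time in 4OHT; the cause was not tested beyond the pair check. Beside these, the block made 24 results on single genes and lists pass and 2 fail. Pairing by number was not detected at day 2 or between days. At day 2, 2 of 8 libraries correlated best with their own number, between days 1 in DMSO and 4 in 4OHT. Leaving out 1 library gave 3736 to 5151 genes at day 2, 3001 to 4041 at day 4, 7556 to 8514 and 6632 to 8450 for time, and 94 to 727 for the interaction. The interaction count moved by more than 1.5 times without any library except DMSO day 4 replicate 4 (190) and 4OHT day 4 replicates 1 (300) and 2 (405); it was 131, 105, 116 and 727 without DMSO day 2 replicates 1 to 4, 183, 538, 94 and 117 without 4OHT day 2 replicates 1 to 4, 130, 165 and 119 without DMSO day 4 replicates 1 to 3, and 111 and 481 without 4OHT day 4 replicates 3 and 4. For single genes and lists, 7022 of 7489 values kept their side of the threshold, 367 lost it (163 with a library left out, 81 with an estimated correlation) and 100 gained it. Of the genes named, Clca3b and Hk1 lost their day 4 call in 6 of 8 fits with a library left out, and Cdkn1a in 4.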

Other observations

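All gene family tests, and the tests of a lag in every gene, of a sterol response, of DNA damage and of the Hnf4a level, were chosen after the results were seen; the test of a partial lag and the splits were set before. Gene families, taken as symbols with the same letters before the first digit and at least 8 tested members, were searched for a shared change (226 families at day 2 and 231 at day 4). Annexins rose in 10 of 12 cases and fell in 0 at day 2 (median log2 0.62) and in 11 of 12 at day 4 (median log2 1.01). Keratins rose in 13 of 24 and fell in 1 at day 2 (median log2 0.47), and rose in 10 of 17 and fell in 2 at day 4. Synaptotagmins, which bind calcium at membranes, rose in 6 of 10 and fell in 1 at day 2 (median log2 0.65), and rose in 5 of 10 and fell in 0 at day 4 (median log2 0.82). Carboxylesterases fell in 9 of 14 and rose in 1 at day 2 (median log2 -0.50), but fell in 2 and rose in 3 at day 4 (median log2 0.01, camera adjusted p = 0.768). Mcm genes of DNA replication fell in 9 of 10 at day 4 (median log2 -0.32), and fell in 3 and rose in 1 at day 2 (camera adjusted p = 0.463). Of the annexins 5 and of the keratins 7 at day 2 were members of a fixed list, of the carboxylesterases 5, of the Mcm genes 6 and of the synaptotagmins 0. The changes given without a camera value passed camera, and none passed with an estimated correlation, where the adjusted p was 0.234, 0.292, 0.325 and 0.986 for annexins, keratins, synaptotagmins and carboxylesterases at day 2, and 0.710, 0.603, 0.556 and 0.948 for annexins, keratins, synaptotagmins and Mcm genes at day 4.

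Fetal and regeneration genes were higher in 4OHT organoids at both days and fell with time in DMSO, so 4OHT organoids may lag behind. A lag in every gene would leave out the same share of the DMSO time change in fetal and in 26 glycolysis and hypoxia genes of 4OHT day 4 libraries. Against same-numbered DMSO libraries, which the pair check pairs at day 4, the shares were 0.87 (0.63 to 1.2 over libraries) and 0.03 (-0.16 to 0.12). The difference was 0.84 (95% interval over libraries 0.26 to 1.42), which excluded equal shares for these genes in the paired comparison. Against the mean of DMSO day 4, which ignores the pairing, the difference was 0.83. Its interval of -0.08 to 1.74 did not exclude equal shares, although the library ranges (0.6 to 1.16 and -0.36 to 0.45) did not overlap. The rule written for this test asked for both intervals to exclude equal shares, so a lag in every gene stays open. The 25 cholesterol synthesis genes had a median of 0.05 at day 2 (bootstrap interval over genes 0.02 to 0.1), with 2 higher and 2 lower. At day 4, 0 were higher and 0 lower. These values argue against more than a small joint rise of these genes at the days measured. Earlier times were not measured, so an earlier sterol response to 4OHT itself stays open. A lag in part of the genes gave what it predicts over 6 splits. In these the 2 effects shared no library, and no replicate number among day 4 libraries, while the time effect used every DMSO day 2 library. The day 4 effect correlated across genes with the DMSO time effect at -0.65 to -0.56. With all libraries the covariance was -0.107, against -0.004 simulated from shared controls alone. However, genes are not independent replicates, and loss of Hnf4a could give the same. DNA damage from CreERT2 activity and loss of Hnf4a cannot be told apart (p53 target median 0.25 at day 2, bootstrap interval over genes 0.19 to 0.52, and -0.41 with time in DMSO), since no organoids with CreERT2 and without a floxed allele were analysed here, and an effect of 4OHT itself stays open for the same reason.

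Hnf4a RNA remained at 50.3% of control at day 2 and 48.6% at day 4. If 50% of the cells had kept intact Hnf4a and control expression of every gene, no gene could fall further than by that share beyond its error. At day 2, 6 genes had an upper 95% limit of the log2 fold change under -1.1, Cps1 among them at 31.2% of control (upper limit 34.3%), which argues against such a mixture. The evidence is thin: the bound of more than 5 genes was set after the largest falls had been seen and was passed by 1 gene, and at day 4 only 3 genes were below the limit, which decides nothing by that bound, although Cps1 was again at 34.4% of control (upper limit 39.4%). Reads from Hnf4a exons outside the deleted part (log2 -0.99 at day 2) cannot be told apart from intact transcript, since the tables hold 1 count per gene.

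Chance as the source of the counts of changed genes is argued against at day 2 and for both time comparisons, as far as 35 splits can tell. The smallest share that they can give is 1 of 35. Every other split mixes the groups, which widens the spread within its sides and favours low counts. The splits also do not cover the spread between separate cultures. In 1 of 35 splits, the real one, the count was as large at day 2 (4950, highest other 0), for time in DMSO (8605, highest other 0) and for time in 4OHT (7880, highest other 0). At day 4 the real split was also the only 1 of 35 (3967, highest other 400), but the replicate numbers pair these libraries. The 400 genes came from the split of replicates 1 and 2 from replicates 3 and 4, which parts no pair. Only 8 splits part every pair as the real one does, too few for a share under 0.05, and the highest other of them gave 0. For the interaction, 2 of 100 splits gave as many genes, the real one with 278 and another with 564. That other split kept replicates 3 and 4 of both day 4 groups together, along the structure of the day 4 pairs, so the share of splits is not taken to exclude chance for the interaction. With a block per replicate number and day the interaction count was 1850.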
